A study of Mus musculus with 12 samples.

How the data were processed

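Total RNA from whole hearts of male C57BL/6 mice was measured on 12 Agilent whole mouse genome arrays with 1 colour (Cy3), 1 array per heart and 3 hearts in each of 4 groups. Per the labels' protocols, RNA was taken with a column kit including a DNase step, and labelled cRNA was made from 500 ng of total RNA. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 9.5. Per the file headers, the deposited scanner files hold the processed signal, an intensity in which spatial and multiplicative trends of the array were removed, dim spots took a surrogate value and local background was not subtracted. The deposited value table equals that processed signal, a linear intensity with no step between arrays; the largest relative difference between the table and the files was 0.

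Groups were taken from the labels: cardiomyocyte-specific glucocorticoid receptor knockout (cardioGRKO) and Cre-negative floxed littermates (GRflox), at 1 and 2 months. Each array had 45018 features, of which 1639 were controls and were left out. Spots marked as non-uniform were left out as well, between 3 and 310 per array. Spots of the same probe were averaged, which gave 41174 probes, and a probe entered if it was well above background on at least 3 of the 12 arrays. Probes took current mouse gene names, matched to the GRCm38.p6 annotation, through the RefSeq accession for 22944 probes, a current symbol for 6664, another accession for 54 and a synonym for 3072, while 8440 kept the name in the files. Each gene was represented by its entering probe with the highest mean over all arrays, which left 21929 genes. Probe positions are those of the array annotation, on mouse build mm7.

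The log2 processed signal minus the 75th percentile of the array was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 12 arrays in the same fit. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, and a gene passed with an adjusted p under 0.05. The comparisons were the knockout against its controls at each age, the difference between those effects, and 2 months against 1 month within each genotype. Errors given with log2 fold changes are standard errors (SE) of the fit, and errors of group levels are SD over 3 hearts. Where a probe was not well above background on any array of a group, its fold is a lower bound under the main processing. For it each such array was set to its dimmest well-above-background probe or to its own value, whichever was higher.

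A total of 40 gene lists was tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated for each list, with adjustment over the lists of a comparison. These covered heart muscle function and metabolism, steroid and stress responses, matrix, growth, and markers of other cell types and neighbouring tissues. The set tests used 21459 genes, since 470 genes lacked a value on at least 1 array. A list score on an array is the median over the list of each gene's log2 signal minus its mean over the 12 arrays. The overlap of calls between ages was tested with a one-sided Fisher exact test over genes, which are not independent replicates.

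The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Nr3c1, the 10 largest rises and 10 largest falls at each age among genes that passed, bear a proper symbol and have groups that do not overlap, 5 of each for the age comparisons, up to 10 for the difference between ages, up to 4 members of each list that passed or otherwise up to 2 given as values, and 18 heart and glucocorticoid genes whether or not they passed. Some genes that the rule names are not reported here.

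Alternatives covered 3 other scalings, the deposited table, 2 other filters on dim probes, 2 other ways to combine probes, slide and replicate terms, another moderation of variances, the 6 compared arrays alone, a fold of at least 1.5, and leaving out each array. Leaving out the arrays of the second scan day, leaving out the 3 arrays that stood apart, scan day as a block and array weights were added after the data were seen. The fit was tested on simulated data with each gene's mean and spread from these arrays, independent noise and 200 changed genes per comparison. For the knockout at 1 month 52% of changes of 1 log2 unit and 69% of changes of 2 were found. At 2 months 43% and 64% were found, with 6 and 11 false calls at the 2 ages. The simulated data held no slide, scan day or correlation between genes, so these shares and false calls may not hold for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays, 3 per group, limits the precision of every value.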

Results

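The series asks which transcripts differ in the heart when the glucocorticoid receptor gene is removed from cardiomyocytes. Mice with a floxed receptor gene carried Cre recombinase under the alpha myosin heavy chain promoter (cardioGRKO), and their Cre-negative floxed littermates (GRflox) served as controls. Since no control carried Cre, the effects of Cre and of receptor loss were not separable. Whole hearts of 3 mice per genotype were profiled at 1 month and at 2 months, 12 arrays in all. The 75th percentile of the processed signal lay between 885.8 and 1549.1 intensity units per array. Correlations between arrays ran from 0.937 to 0.987 over all pairs and from 0.950 to 0.986 within a group.

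The 12 arrays came from 4 slides, and group and slide were partly mixed. Slide 1 held the 1-month controls alone. Slide 2 held cardioGRKO_1month replicates 2 and 3 with GRflox_2month replicates 1 and 2, and slide 3 held GRflox_2month replicate 3 with cardioGRKO_2month replicates 1 and 2. Slide 4 held cardioGRKO_1month replicate 1 and cardioGRKO_2month replicate 3 and was scanned on a second day. Those last 2 arrays had 79.4% and 79.6% of probes well above background and GRflox_2month replicate 2 had 82.2%, against 67.5% to 74.0% on the other arrays. The slide 4 pair also had the highest T and B lymphocyte marker scores, 0.80 and 0.70. Marker scores of tissue that borders the heart varied within groups, from -2.42 to 1.54 for adipocytes and from -1.94 to 2.63 for lung.

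Nr3c1, which encodes the glucocorticoid receptor, fell in the 2-month knockouts by 1.15 on the log2 scale (SE 0.13, 2.22-fold, limma adjusted p = 0.0118, n = 3 hearts per group). At 1 month it went from 2.35 ± 0.27 to 1.35 ± 0.05 (SD; 95% interval of the log2 fold change -1.29 to -0.71, limma adjusted p = 0.0686, n = 3) and missed the threshold. On the probe that represents the gene, the groups did not overlap at either age. The array carries 4 Nr3c1 probes, on chromosome 18 (mm7) at 39787242 to 39787301, 39789494 to 39789553, 39790613 to 39790672 and 39790806 to 39790865, each well above background on all 12 arrays. In that order the knockout signal was 0.5002, 0.576, 0.656 and 0.566 of the control signal at 1 month, and 0.451, 0.467, 0.549 and 0.404 of it at 2 months. The labels do not give the floxed exons, so it is open whether these probes lie in the deleted part. The mean signal of all 4 was lower in the knockouts at both ages, wherever they lie. On the probe at 39790613 to 39790672 the 2-month groups overlapped, with cardioGRKO_2month replicate 3 at -2.28 and GRflox_2month replicate 3 at -2.40. Whole hearts also hold other cells in which the gene is intact.

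At 1 month, 6 genes differed between knockout and control hearts, and the largest change was in a myosin gene. Myh7, the slow (beta) myosin heavy chain, rose 7.05-fold (log2 2.82, SE 0.22, limma adjusted p = 0.00588, n = 3 per group), from 4.54 ± 0.37 to 7.35 ± 0.09 (SD). Phyhd1, which encodes a phytanoyl-CoA dioxygenase domain protein, fell 2.52-fold (adjusted p = 0.00588). Csdc2, a cold shock domain RNA-binding protein, fell 2.55-fold (adjusted p = 0.0124), and Myot, the Z-disc protein myotilin, fell 2.62-fold (adjusted p = 0.0299). Ddit4l, a relative of the mTOR inhibitor Ddit4, rose 1.58-fold (log2 0.66, SE 0.08, adjusted p = 0.0407). The last of the 6 genes that passed, outside the naming rule and named after its values were seen, was the probe A_52_P764117, which has no gene name in the files and lies on chromosome 16 (mm7) at 4860399 to 4860458; it rose by log2 1.43 (adjusted p = 0.0243). A total of 3 genes rose and 3 fell, 1339 had an unadjusted p under 0.05 where 1096 were expected by chance, and 17.7% of genes had groups that did not overlap where chance gives 10%.

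Classical glucocorticoid targets did not pass at 1 month. Ptgds, the lipocalin-type prostaglandin D synthase, had a log2 fold change of -1.32 (SE 0.18, adjusted p = 0.0849), Fkbp5 of -0.55 (SE 0.34), Tsc22d3 of -0.19 (SE 0.16), Per1 of -0.40 (SE 0.37), Klf15 of 0.08 (SE 0.15) and Lcn2 of -0.70 (SE 0.68). Of the 41 measured glucocorticoid-induced genes, 0 rose and 0 fell by limma over all genes, 27 leaned lower, and 2 (Ptgds and Ampd3) were lower when adjusted over the list alone. Camera placed the list lower (median -0.10, adjusted p = 0.0384), which was lost with an estimated correlation (adjusted p = 0.436 with an estimated correlation). The 14 corticosteroid receptor and metabolism genes had a median of -0.11 (adjusted p = 0.0262; adjusted p = 0.369 with an estimated correlation), with 0 members past over all genes and 1, Nr3c1, lower when adjusted over the list alone. The mineralocorticoid receptor gene Nr3c2 had a log2 fold change of 0.98 (SE 0.64). Without cardioGRKO_1month replicate 3 or GRflox_1month replicate 1 both list calls were lost (adjusted p up to 0.145 for the receptor list). The induced list was also lost without GRflox_1month replicate 2 or cardioGRKO_1month replicate 1 (up to 0.292) and with scan day as a block (median -0.09, adjusted p = 0.0608). Of 13 alternatives that left out no single array, 8 ended the receptor call (up to 0.232), median centring (0.0836) and leaving out the second scan day (0.0545) among them, and 7 ended the induced call (up to 0.485).

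Genes of contraction and energy supply leaned lower at 1 month as groups, without members that passed except Myot. Among 27 sarcomere genes, 1 fell, 0 rose and 22 leaned lower, with the same 1 adjusted over the list alone (median -0.21, camera adjusted p = 3.13e-06; adjusted p = 0.398 with an estimated correlation). Oxidative phosphorylation had 45 of 49 members below 0, with Sdhb at -0.27 and Atp5g1 at -0.39, and fatty acid oxidation 30 of 35, with Acot1 at -1.07 and Acot2 at -0.58. No member of either passed over all genes or adjusted over the list alone (medians -0.15 and -0.18, adjusted p = 7.22e-08 and 4.77e-07; adjusted p = 0.454 and 0.369 with an estimated correlation). Cell cycle genes were also lower, 37 of 39 below 0 with a median of -0.40 (adjusted p = 2.74e-11; adjusted p = 0.369 with an estimated correlation), with 0 members past by either count and Mcm6 at -0.45 (SE 0.11); without GRflox_1month replicate 2 the median was -0.22. The endothelial markers had a median of -0.17 over 20 genes (adjusted p = 7.89e-05; adjusted p = 0.369 with an estimated correlation) and 0 members past by either count. Under quantile scaling the sarcomere median shrank to -0.01 and that of oxidative phosphorylation to -0.02. These 5 lists kept their camera call when any 1 array was left out and with scan day as a block, where their medians were -0.15, -0.11, -0.15, -0.45 and -0.13 in the order given. Normexp background with quantile scaling ended 12 of the 14 list calls of this age, all but those of cell cycle and immediate early genes, and quantile scaling alone ended 10. Of the 5 lists only cell cycle kept its call in each of the 13 alternatives (adjusted p up to 4.63e-09), while those of sarcomere genes (0.394), oxidative phosphorylation (0.527), fatty acid oxidation (0.0711) and endothelial markers (0.193) were lost in at least 1.

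A further 7 lists were lower by camera at 1 month, each with an adjusted p of at least 0.369 with an estimated correlation. They were ventricular cardiomyocyte markers (median -0.20, adjusted p = 0.000694; Hey2 at -0.66 was lower adjusted over the list alone), immediate early genes (-0.10, 0.00636), glycolysis (-0.07, 0.00979; Pfkfb1 lower adjusted over the list alone), and calcium handling (-0.08, 0.0114). The others were smooth muscle and pericyte markers (-0.08, 0.0196), the dystrophin complex (median -0.08 but mean -0.00, 0.0434) and interferon response genes (-0.12, 0.0443). In calcium handling 4 genes were past when adjusted over the list alone, with Casq1 (1.21) and Itpr1 (0.41) higher, and Jph2 (-0.35) and the ryanodine receptor Ryr2 (-0.36) lower. None of the 7 had a member past over all genes. Without cardioGRKO_1month replicate 1 the calls of all but the interferon list were lost, with adjusted p up to 0.0615 for ventricular markers and up to 0.216 for calcium handling. Other arrays that ended a call were GRflox_1month replicate 3 for immediate early genes (up to 0.127), GRflox_1month replicate 1 for glycolysis (up to 0.128), and cardioGRKO_1month replicate 2 for smooth muscle (up to 0.0659). The dystrophin call was also lost without GRflox_1month replicate 2 or 3, cardioGRKO_1month replicate 3 or GRflox_2month replicate 1 (up to 0.357). The interferon call was lost without GRflox_1month replicate 2, cardioGRKO_1month replicate 3, GRflox_2month replicate 3 or cardioGRKO_2month replicate 1 or 2 (up to 0.466), and without the first of these its direction turned. With scan day as a block, calcium handling (median -0.06, adjusted p = 0.0733), glycolysis (-0.06, 0.102), smooth muscle (-0.10, 0.102) and the dystrophin complex (-0.06, 0.447) lost their calls. With quantile scaling the median of glycolysis was 0.03, the other direction. Of the 13 alternatives, 2 ended the call of immediate early genes (up to 0.0679), 4 that of ventricular markers (0.839), 4 interferon (0.394), 6 glycolysis (0.917), 7 smooth muscle (0.399), 8 calcium handling (0.448) and 10 the dystrophin complex (0.760).

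Among hypertrophy markers at 1 month, only Myh7 passed: of 28 genes of the fetal and hypertrophy list 1 rose and 0 fell, 2 rose and 1 fell when adjusted over the list alone, and the list did not move (median -0.06, mean 0.11, camera adjusted p = 0.784). Natriuretic peptide genes Nppa (-0.12, SE 0.18) and Nppb (-0.07, SE 0.34), skeletal actin Acta1 (0.84, SE 0.34), Ankrd1 (0.41, SE 0.20) and Myh6, the fast (alpha) myosin (-0.26, SE 0.14), did not pass, nor did Atp2a2 (-0.15, SE 0.15), Pln (-0.15, SE 0.12), Col1a1 (0.05, SE 0.23) or Postn (-0.26, SE 0.24).

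The count of 6 at 1 month was sensitive to single hearts: it was 0 without cardioGRKO_1month replicate 1 or replicate 2, 2 without GRflox_1month replicate 2, and 3 without cardioGRKO_1month replicate 3, GRflox_2month replicate 2 or 3, or cardioGRKO_2month replicate 1 or 2. All 6 genes kept their direction in each of these fits with an unadjusted p under 0.05. Of the 14 lists, 11 had a median that changed by more than 1.5 times without 1 of the arrays. Slide 1 held every 1-month control and no knockout, so slide and genotype cannot be told apart from the 1-month arrays alone. Yet 5 of the 6 genes also passed at 2 months, where no array came from slide 1, and the sixth (Ddit4l) kept its direction there. The count was 0 without the arrays of the second scan day and 4 with scan day as a block. Higher and lower calls were 3 and 8 with normexp background and quantile scaling and 3 and 6 with quantile scaling alone, against 3 and 3. Centring on the median shifted the median of all genes to -0.18 and left 0 calls by limma, with 691 genes at an unadjusted p under 0.05.

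At 2 months, 29 genes differed between knockout and control hearts, 17 higher and 12 lower. Myh7 was again the largest named rise, 5.02-fold (log2 2.33, SE 0.22, limma adjusted p = 0.00589, n = 3 per group), from 5.58 ± 0.36 to 7.91 ± 0.17 (SD). Of the skeletal muscle markers, which did not move as a list (2 of 22 higher, 0 lower, camera adjusted p = 0.236), Casq1, the fast-fibre calsequestrin, rose 4.45-fold (adjusted p = 0.0148, 2 of 3 control hearts measured) and Mybpc2, the fast myosin-binding protein C, rose by log2 1.09 (SE 0.14, adjusted p = 0.0336). Kcnj14, an inward rectifier potassium channel, rose 3.31-fold (adjusted p = 0.00822), and Bcl2, an inhibitor of apoptosis, rose 2.48-fold on 1 probe (adjusted p = 0.0467), while its other probes gave log2 0.02 and 0.57. Pdzd3 rose 2.68-fold (adjusted p = 0.0118) and Meig1 3.21-fold (adjusted p = 0.0348), with Mycbpap (2.07-fold), the ubiquitin hydrolase Uchl1 (1.97-fold) and the polymerase I subunit Polr1e (1.80-fold).

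Falls at 2 months included the 3 genes that fell at 1 month. Phyhd1 fell 3.09-fold (log2 -1.63, SE 0.11, limma adjusted p = 0.00206, n = 3), Csdc2 fell 3.03-fold (adjusted p = 0.0034) and Myot fell 3.73-fold (adjusted p = 0.0034). Ptgds fell 3.31-fold (log2 -1.73, SE 0.18, adjusted p = 0.0112), and Cngb3, a cyclic nucleotide-gated channel subunit, fell 3.69-fold (adjusted p = 0.00529). Pfkfb1, which makes and breaks down fructose 2,6-bisphosphate, fell 2.62-fold (adjusted p = 0.0348), and Whrn fell 1.77-fold on 1 probe (adjusted p = 0.0306), with the other probe at log2 -0.51. Prr27 was at least 11.7-fold lower and Klk1b16, a tissue kallikrein, at least 5.51-fold lower in the knockouts (both limma adjusted p = 0.0118). These bounds apply to the main processing only. Over the alternatives the log2 fold change ran from -3.89 to -0.81 for Prr27 and from -3.18 to -0.39 for Klk1b16. Both genes were well above background in the 3 control hearts of 2 months and in no other heart. Of the 29, the probes A_52_P764117 (log2 1.64) and A_52_P836919 (1.34; chromosome 14, mm7, 58223932 to 58224473) had no gene name. In all, 1708 genes had an unadjusted p under 0.05 where 1096 were expected, and 12.8% had groups that did not overlap where chance gives 10%.

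**Figure D1:**
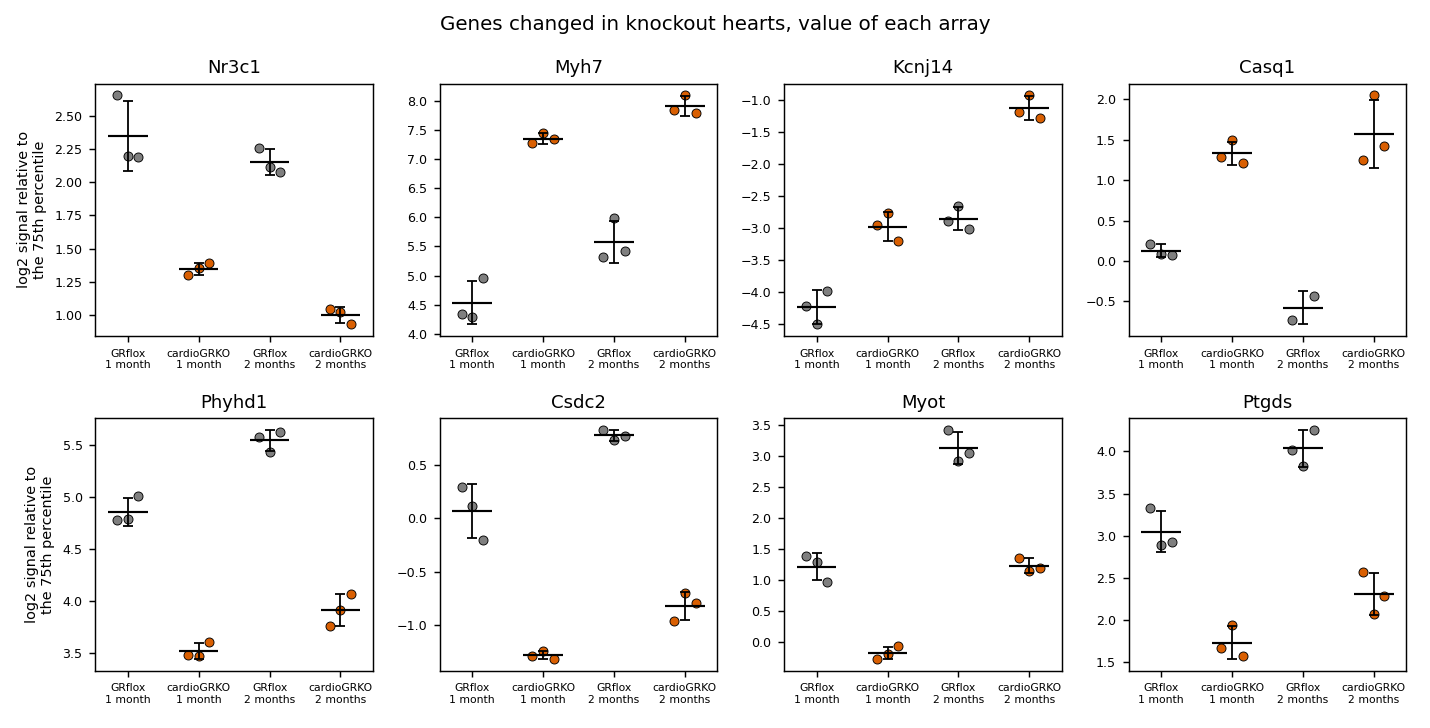
Expression of Nr3c1, Myh7 and other genes named in the knockout comparisons, as log2 processed signal minus the array's 75th percentile, in GRflox and cardioGRKO hearts at 1 and 2 months. Each point is 1 heart and lines give the mean with SD (3 hearts per group, 2 for Casq1 in the 2-month controls); Myh7 lies higher and Phyhd1, Csdc2 and Myot lie lower in every knockout heart than in every control heart of the same age.

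The hypertrophy list was higher at 2 months. Of 28 fetal and hypertrophy genes, 1 (Myh7) rose and 0 fell over all genes, 7 rose and 0 fell when adjusted over the list alone, and camera placed the list higher (median 0.10, adjusted p = 0.00124; adjusted p = 0.642 with an estimated correlation). Acta1 was at log2 1.35 (SE 0.34), Nppb at 1.10 (SE 0.34), Ankrd1 at 0.83 (SE 0.20) and Ccn2 at 0.79 (SE 0.20) without passing over all genes, while Nppa was at 0.20 (SE 0.18) and Myh6 at 0.04 (SE 0.14). Within slide 3, which held 1 control and 2 knockouts of this age, the list median was 0.20, and with slide as a block it was 0.12 (adjusted p = 0.00944). The call was lost without GRflox_2month replicate 2 or cardioGRKO_2month replicate 2 (adjusted p up to 0.0944) and, of 15 other alternatives, in 1, without the 3 arrays that stood apart (0.0703). The fit within slide 3 took its spread from the knockouts and the 1-month arrays and assumed that the lone control varied like them, so its list medians are given here without p-values; there 5 of the 9 list calls ended, namely those of fatty acid oxidation, glucocorticoid-induced, corticosteroid receptor, endothelial and macrophage genes. Ryr2, at -0.54 (SE 0.10, adjusted p = 0.0990), was the only calcium handling gene lower when adjusted over the list alone, and Casq1 the only one that rose among 31 by either count (camera adjusted p = 0.415). Atp2a2 was at 0.10 (SE 0.15), Pln at -0.15 (SE 0.12), Col1a1 at 0.23 (SE 0.23) and Postn at -0.43 (SE 0.24).

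Fuel use, steroid and vessel genes leaned lower at 2 months. Fatty acid oxidation had 32 of 35 members below 0 (median -0.15, camera adjusted p = 3.87e-05; adjusted p = 0.642 with an estimated correlation), 0 past over all genes and 1 lower adjusted over the list alone, Acot1 at -1.42 (SE 0.29). Within slide 3 the list's median was -0.08, and with slide as a block -0.10 (adjusted p = 0.0331). Of 41 glucocorticoid-induced genes Ptgds alone fell, by either count, and 0 rose (median -0.11, adjusted p = 0.0183; adjusted p = 0.642 with an estimated correlation); Fkbp5 was at -0.61 (SE 0.34), Tsc22d3 at -0.11 (SE 0.16), Per1 at -0.45 (SE 0.37), Klf15 at -0.32 (SE 0.15) and Lcn2 at -1.31 (SE 0.68). That call was lost without GRflox_2month replicate 1 (adjusted p = 0.575) and with slide as a block (median -0.10, 0.0912), and within slide 3 the median was -0.09. The 14 corticosteroid receptor genes had Nr3c1 lower by either count and 0 higher (median -0.09, adjusted p = 0.0254; adjusted p = 0.642 with an estimated correlation), with medians of -0.18 within slide 3 and -0.20 with slide as a block (adjusted p = 0.02); Nr3c2 was at 0.00 (SE 0.64). This call was lost without GRflox_2month replicate 1 or 3 or cardioGRKO_2month replicate 1 (up to 0.140) and with median centring (0.123). Endothelial markers had a median of -0.16 (adjusted p = 0.00121; adjusted p = 0.642 with an estimated correlation), -0.09 within slide 3 and -0.11 with slide as a block (0.0331), with 0 members past by either count, and lost the call without cardioGRKO_2month replicate 3 (0.074). With scan day as a block, the endothelial and the glucocorticoid-induced call each had an adjusted p of 0.0534. The 15 alternatives ended the fatty acid call 2 times, the receptor and the endothelial call 3 times each and the induced call 5 times.

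A second set of lists moved at 2 months with 0 members past over all genes, apart from Bcl2. Interferon response genes had 27 of 30 members below 0 (median -0.22, camera adjusted p = 0.00106; adjusted p = 0.859 with an estimated correlation), with Ddx58 at -0.38 and 0 members past adjusted over the list alone; the median was -0.34 within slide 3 and -0.38 with slide as a block (adjusted p = 3.46e-06). Without GRflox_2month replicate 3 the adjusted p was 0.0606. Cell cycle genes had 33 of 39 members above 0 (median 0.31, adjusted p = 0.000264; adjusted p = 0.859 with an estimated correlation), with Ccne1 at 0.41 and 0 members past by either count; the median was 0.30 within slide 3 and 0.14 with slide as a block (0.0109). Both calls held in all 15 alternatives. Leaving out 1 array brought the cell cycle median down to 0.20 (without cardioGRKO_2month replicate 1) and the interferon median to -0.13 (without GRflox_2month replicate 2). Apoptosis and p53 targets had a median of 0.16 over 33 genes (adjusted p = 0.0193; adjusted p = 0.642 with an estimated correlation), 1 member higher over all genes, and 3 higher and 1 lower (Bnip3, at -0.54) when adjusted over the list alone. Within slide 3 its median was 0.11 and with slide as a block 0.12 (0.0116). Its call was lost without GRflox_2month replicate 2 or cardioGRKO_2month replicate 1 (up to 0.317) and in 4 of the alternatives (up to 0.197), median centring (0.0999) among them. Macrophage markers had 18 of 22 members above 0 (median 0.09, adjusted p = 0.0254; adjusted p = 0.859 with an estimated correlation) and 0 members past by either count. Their median was 0.06 within slide 3, and 7 of the alternatives ended their call. It was lost with slide as a block (median 0.04, 0.454), with median centring (0.253) and without GRflox_2month replicate 2 or cardioGRKO_2month replicate 1 or 2 (up to 0.652).

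The count of 29 at 2 months varied with the hearts used and with slide terms. It was 10 without cardioGRKO_2month replicate 2 or 3, and 11, 12 and 13 without GRflox_2month replicates 2, 3 and 1. It was 16 without cardioGRKO_1month replicate 2 or cardioGRKO_2month replicate 1. It was 17 without GRflox_1month replicate 2 or cardioGRKO_1month replicate 3, 18 without cardioGRKO_1month replicate 1 and 19 without GRflox_1month replicate 3. It was 8 without the arrays of the second scan day, 25 with scan day as a block, and 0 within slide 3 or with slide as a block, where limma gave 890 and 950 genes at an unadjusted p under 0.05. All 28 of the 29 genes that could be fitted within slide 3 kept their direction there, as did all 26 that could be fitted with slide as a block. As a median their log2 fold changes were 1.04 times and 1 times their values in the main fit, which shares these arrays. Centring on the median left 1 gene higher and 2 lower. Of the 9 lists, 8 had a median that changed by more than 1.5 times without 1 of the arrays.

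The knockout effects at the 2 ages shared named genes. Of the 3 genes higher at 1 month, 2 were among the 17 higher at 2 months (Myh7 and A_52_P764117; 0.00233 expected, one-sided Fisher exact p = 1.7e-06), and all 3 genes lower at 1 month (Csdc2, Myot and Phyhd1) were among the 12 lower at 2 months (0.00164 expected, one-sided Fisher exact p = 1.25e-10). The exact test treats genes as independent, which they are not. It also treats the 2 sets of calls as independent, although both used the same estimate of each gene's spread. At an adjusted p under 0.1 at both ages, 11 genes were shared, adding Kcnj14, Ddit4l and A_52_P836919 among the rises and Nr3c1, Ptgds and Whrn among the falls. Whrn rests on 1 probe here, since its other probe gave log2 0.03 at 1 month and -0.51 at 2 months. A_52_P836919 was named after its values were seen. The count of 5 was 0 without cardioGRKO_1month replicate 1 or 2 and 2 without GRflox_1month replicate 2. It was 3 without cardioGRKO_1month replicate 3, GRflox_2month replicate 2 or 3, or cardioGRKO_2month replicate 1 or 2, and 0 without the second scan day.

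**Figure D2:**
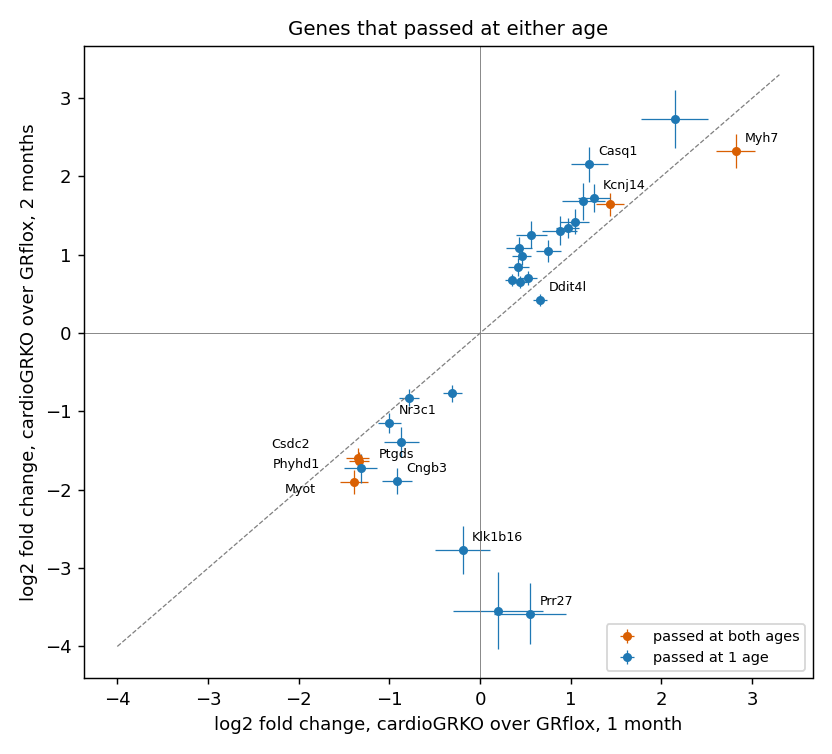
Log2 fold change of knockout over control at 1 month (horizontal axis) and at 2 months (vertical axis) for the genes that passed at either age, with SE bars from the limma fit and a dashed line of equal change. The 5 genes that passed at both ages (orange) lie near the line, while Prr27 and Klk1b16, near background in 3 of the 4 groups, lie far below it.

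By limma 0 genes differed in their knockout effect between the ages, with 292 genes at an unadjusted p under 0.05 where 1096 were expected and a smallest adjusted p of 0.767. On the simulated data this comparison found 26% of changes of 1 log2 unit and 60% of changes of 2. The count of 0 thus does not show that the effects were equal. The smallest adjusted p was that of 1 gene. This gene was Prr27, which was well above background only in the 2-month controls, so no size is given. Myh7 had a difference of -0.49 (SE 0.31, adjusted p = 1). The cell cycle list differed between the ages: 37 of 39 genes had a more positive effect at 2 months than at 1 month (median 0.61, camera adjusted p = 2.24e-27; adjusted p = 0.175 with an estimated correlation), with Mcm5 at 0.79 (SE 0.20) and Prc1 at 1.31 (SE 0.38), and 0 members past over all genes or adjusted over the list alone. Median centring moved the median of all genes in this comparison to 0.16.

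A further 7 lists had a more positive knockout effect at 2 months by camera, all lost with an estimated correlation (adjusted p of 0.220 to 0.831) and each with 0 members past by either count. Fetal and hypertrophy genes (median 0.20, adjusted p = 3.6e-05) included Nppb at 1.17 and Ccn2 at 0.87, and their call held without any 1 array. Oxidative phosphorylation (0.12, 2.55e-05, with Ndufb3 at 0.32) and sarcomere genes (0.13, 0.000308, with Synpo2l at 0.42 and Myot at -0.51) lost theirs without GRflox_1month replicate 3 or cardioGRKO_1month replicate 1 (up to 0.148 and 0.149). Ventricular markers (0.14, 0.00753, with Hey2 at 0.34) were lost without those arrays or cardioGRKO_2month replicate 2 (up to 0.401). Matrix genes (0.11, 0.00155, with Thbs4 at 0.30) were lost without GRflox_1month replicate 2, GRflox_2month replicate 2 or cardioGRKO_2month replicate 2 (up to 0.847). Apoptosis genes (0.07, 0.00856, with Birc5 at 0.93 and Bcl2 at 0.43) were lost without GRflox_1month replicate 2, cardioGRKO_1month replicate 1, GRflox_2month replicate 2 or cardioGRKO_2month replicate 1 (up to 0.543). Macrophage markers (0.07, 0.0402, with Cd68 at 0.35 and Adgre1 at 0.31) were lost without any of those 4, GRflox_1month replicate 1, cardioGRKO_1month replicate 3 or cardioGRKO_2month replicate 2 (up to 0.859). Either quantile scaling put the medians of oxidative phosphorylation and ventricular markers below 0, and normexp background with quantile scaling put that of sarcomere genes at -0.03. Each of these scalings ended 6 of the 8 calls, all but those of fetal and cell cycle genes, and without the 3 arrays that stood apart the fetal call was lost too (0.0985); cell cycle alone held in all 12 alternatives. Of the 8 medians, 7, all but that of cell cycle genes, changed by more than 1.5 times without 1 of the arrays.

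Growth in the controls from 1 to 2 months came with a broad fall of dividing-cell genes. Of 483 genes that changed, 173 rose and 310 fell, and 366 changed at least 1.5-fold. Prc1, which bundles spindle microtubules, fell 5.51-fold (log2 -2.46, SE 0.27, limma adjusted p = 0.00419, n = 3 per age), Aurkb, a mitotic kinase, fell 5.45-fold (adjusted p = 0.0117), Ska1, of the kinetochore, fell 5.10-fold (adjusted p = 0.0112) and Pimreg fell 6.10-fold (adjusted p = 0.0295), with Pbk at log2 -2.41. In the cell cycle list 21 of 39 genes fell, 0 rose and 32 fell when adjusted over the list alone (median -1.30, camera adjusted p = 3.60e-36; adjusted p = 0.0305 with an estimated correlation), among them Cenpe (-2.09), Birc5 (-2.15), Mcm5 (-1.40) and Mcm6 (-1.08).

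Matrix genes and an imprinted growth network fell with age in controls too. Of 51 matrix genes 19 fell and 0 rose, and 33 fell and 1 rose when adjusted over the list alone (median -0.71, adjusted p = 4.09e-29; adjusted p = 0.0343 with an estimated correlation), with collagen genes Col3a1 (-1.59), Col6a2 (-1.04) and Col5a1 (-0.96) and the matrix glycoprotein gene Sparc (-1.33). Col1a1 fell by 1.53 (SE 0.23, adjusted p = 0.0138). In the imprinted list Mest fell by 1.60 (SE 0.11, adjusted p = 0.00159), with Peg3 (-1.03) and Plagl1 (-0.73) also lower and Impact higher (0.66); of 15 genes 4 fell and 1 rose, and 10 fell and 1 rose adjusted over the list alone (median -0.50, adjusted p = 9.31e-08; adjusted p = 0.0305 with an estimated correlation). Apoptosis and p53 targets had 4 of 33 lower and 0 higher, and 11 lower and 1 higher adjusted over the list alone (median -0.13, adjusted p = 0.000109; adjusted p = 0.0305 with an estimated correlation), with Casp8 at -0.54.

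Interferon and several cell-type lists were lower at 2 months in controls by camera. Interferon response genes had 4 of 30 lower, with Rtp4 (-0.78), Usp18 (-0.88), Oasl2 (-0.93) and Ddx58 (-0.65), 0 higher and 17 lower adjusted over the list alone (median -0.51, adjusted p = 7.67e-14; adjusted p = 0.283 with an estimated correlation). Fibroblast markers had 6 of 20 lower and 9 adjusted over the list alone, with Mfap5 at -1.23 (median -0.36, adjusted p = 1.40e-10; adjusted p = 0.114 with an estimated correlation). Smooth muscle and pericyte markers had 2 of 17 lower (Mcam -0.60, Pdgfrb -0.48) and 5 adjusted over the list alone (median -0.32, adjusted p = 0.000723; adjusted p = 0.114 with an estimated correlation), and macrophage markers 1 of 22 by either count (Cd68, -0.61; median -0.28, adjusted p = 6.13e-07; adjusted p = 0.288 with an estimated correlation). None of these 4 lists had a member higher. Endothelial (median -0.24, adjusted p = 6.96e-06) and mesothelial (-0.42, 0.000163) markers had 0 members past by either count and were lost with an estimated correlation (adjusted p = 0.166 and 0.585 with an estimated correlation).

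The largest rises with age in controls were in Prr27, at least 18.0-fold (adjusted p = 0.00352), Klk1b16, at least 7.05-fold (adjusted p = 0.0038), and the neural adhesion gene Cntn5, 7.41-fold (log2 2.89, SE 0.45, adjusted p = 0.0156). Tnip3 rose at least 4.22-fold (limma adjusted p = 0.0386). These bounds apply to the main processing only. Over the alternatives the log2 fold change ran from 0.90 to 4.91 for Prr27 and from 0.32 to 2.99 for Klk1b16. It ran from 0.16 to 2.49 for Tnip3 and from 0.99 to 3.17 for Cntn5. Other named genes that rose were Myot by log2 1.92 (SE 0.15, adjusted p = 0.00352), Cacna1s by 1.28, Clu by 0.96, Gsta1 by 1.52, Pfkfb1 by 1.13, Myh7 by 1.05 (adjusted p = 0.0456), Xirp2 by 0.60, Klf15 by 0.84, Ptgds by 0.99, Cxcl14 by 1.74, Hspb8 by 0.57 and Atf6 by 0.62. Fatty acid oxidation was the only list higher by camera (median 0.27, adjusted p = 0.00106; adjusted p = 0.528 with an estimated correlation), with 0 members past over all genes and 6 higher adjusted over the list alone; centring on the median, which shifted all genes to -0.13, left it at 0.01 (adjusted p = 0.611).

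All 1-month controls shared slide 1 and no 2-month control lay on it, so age and slide cannot be told apart in controls; the 11 list calls held without any 1 array and 9 of them in all 13 other alternatives, the exceptions being fatty acid oxidation and, without the 3 arrays that stood apart, mesothelial markers (0.0514). The medians of apoptosis, smooth muscle and mesothelial genes changed by more than 1.5 times without 1 of the arrays. The number of genes changed with age in controls was 155 without GRflox_1month replicate 2, 190 without replicate 1, 196, 232 and 257 without GRflox_2month replicates 3, 1 and 2, 305 and 304 without cardioGRKO_1month replicates 1 and 3, and 311 without cardioGRKO_2month replicate 2. It was 244 without the second scan day, and centring on the median gave 7 higher and 69 lower. Groups did not overlap in 23.2% of genes where chance gives 10%.

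In the knockouts, 177 genes changed between 1 and 2 months, 71 higher and 106 lower, of which 147 at least 1.5-fold. Grin3b, a glutamate receptor subunit, rose 2.69-fold (log2 1.43, SE 0.15, limma adjusted p = 0.0128, n = 3 per age), the ketone body enzyme Bdh1 rose by log2 2.30 (SE 0.23, adjusted p = 0.0128), and Kcnj14 rose by 1.85 (adjusted p = 0.0128), with Cpxm2 (3.56-fold) and Vwa7 (2.85-fold). Falls were in dividing-cell genes Pbk (3.36-fold, adjusted p = 0.0378), Ect2 (2.97-fold, adjusted p = 0.0440) and Mki67 (log2 -1.54, adjusted p = 0.0271), and in matrix genes Col26a1 (3.13-fold) and Adamts12 (2.93-fold). The size for Adamts12 depended on the processing, with a log2 fold change from -1.86 to -0.10 over the alternatives. The groups did not overlap in 24.6% of genes where chance gives 10%.

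Of the 10 lists lower with age in controls, 9 also had a median below 0 in the knockouts, the exception being apoptosis and p53 targets; 5 are given here and the others below. Of 51 matrix genes 15 fell and 0 rose, and 31 fell and 1 rose adjusted over the list alone (median -0.57, camera adjusted p = 9.20e-22; adjusted p = 0.147 with an estimated correlation), with Col3a1 at -1.45 and Loxl2 at -1.17. Of 39 cell cycle genes 4 fell (Mki67, Tyms, Birc5 and Cenpe) and 0 rose, and 22 fell and 1 rose adjusted over the list alone (median -0.76, adjusted p = 1.98e-16; adjusted p = 0.189 with an estimated correlation). Of 30 interferon response genes Ddx58 (-0.88), Irf9 (-0.58) and Rtp4 (-0.84) fell, 0 rose and 21 fell adjusted over the list alone (median -0.66, adjusted p = 3.98e-18; adjusted p = 0.189 with an estimated correlation). Mest (-1.26) and Peg3 (-0.95) fell in the imprinted list of 15, with 7 lower and 1 higher adjusted over the list alone (median -0.42, adjusted p = 1.27e-07; adjusted p = 0.0705 with an estimated correlation). Fibroblast markers had 4 of 20 lower, and 10 lower and 1 higher adjusted over the list alone (median -0.33, adjusted p = 2.04e-08; adjusted p = 0.189 with an estimated correlation). With slide as a block the medians of these 5 lists were -0.64, -0.86, -0.77, -0.43 and -0.46.

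**Figure D3:**
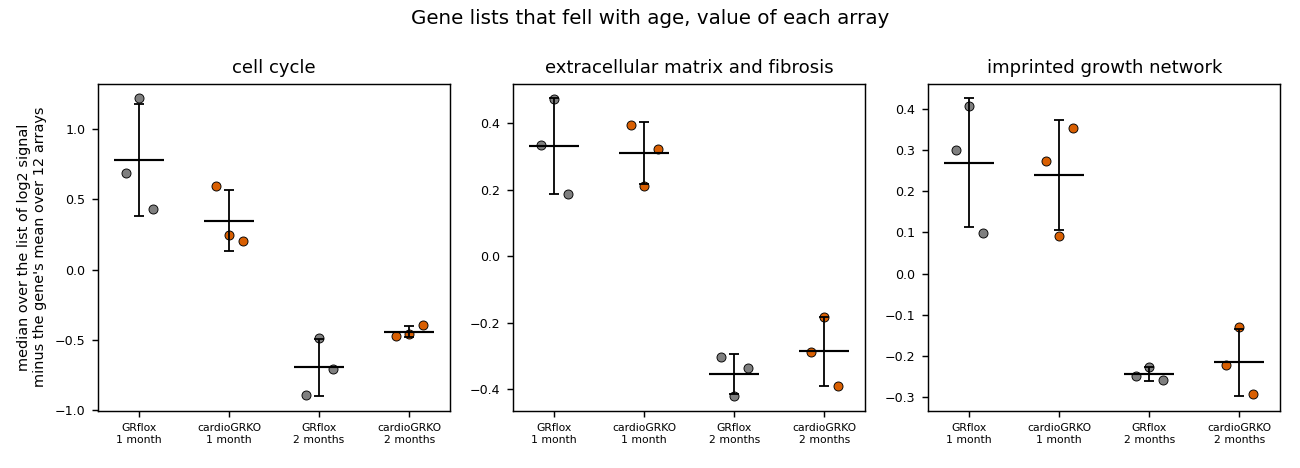
Scores of the cell cycle, matrix and imprinted gene lists on each array, as the median over the list of log2 signal minus the gene's mean over the 12 arrays, for GRflox and cardioGRKO hearts at 1 and 2 months. Each point is 1 heart and lines give the mean with SD (n = 3); the 2-month hearts lie below the 1-month hearts of the same genotype in all 3 lists.

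Muscle and energy genes were higher at 2 months in the knockouts by camera. Sarcomere genes had 1 of 27 higher (Myot, 1.41), 0 lower and 6 higher adjusted over the list alone (median 0.30, adjusted p = 1.55e-07; adjusted p = 0.270 with an estimated correlation). Of 28 fetal and hypertrophy genes Ankrd1 (1.19) and Xirp2 (0.74) rose, 0 fell and 8 rose adjusted over the list alone (median 0.30, adjusted p = 0.000146; adjusted p = 0.270 with an estimated correlation). Oxidative phosphorylation had 48 of 49 members above 0 (median 0.22, adjusted p = 2.76e-08; adjusted p = 0.372 with an estimated correlation) and fatty acid oxidation 29 of 35 (median 0.29, adjusted p = 0.000134; adjusted p = 0.301 with an estimated correlation), with 0 members past by either count. With quantile scaling the oxidative phosphorylation median was 0.02 and that of sarcomere genes 0.10. The oxidative phosphorylation call was lost with either quantile scaling (0.738 and 0.635) and the fatty acid call with median centring (0.0635). Cacna1s rose in the skeletal muscle list (1.24; 2 of 22 adjusted over the list alone, 0 lower; median 0.37, adjusted p = 0.0011; adjusted p = 0.189 with an estimated correlation), and Gsta1 (1.16) and Gstm2 (0.57) in oxidative stress defence (2 of 35 by either count; median 0.14, adjusted p = 0.049; adjusted p = 0.301 with an estimated correlation). With slide as a block the medians were 0.36, 0.27, 0.27, 0.31, 0.34 and 0.14 in the order given, and only oxidative stress defence lost its call (adjusted p = 0.202). It also lost it without any 1 array (up to 0.468) other than GRflox_1month replicate 2, cardioGRKO_1month replicates 2 and 3, and cardioGRKO_2month replicate 3.

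Other lists past camera in this comparison, all lost with an estimated correlation (adjusted p of 0.189 to 0.722), were markers of other cells and 2 pathways. Lower were mesothelial (median -0.70, adjusted p = 9.63e-08), endothelial (-0.23, 1.34e-05), macrophage (-0.19, 0.000534), smooth muscle (-0.18, 0.00677, with Mcam at -0.51), mast cell (-0.43, 0.00677), adipocyte (-1.20, 0.0264) and lung markers (-2.20, 0.0464). Apoptosis and p53 targets had a median of 0.02, a mean of -0.06 and a lower camera call (0.0407), with Casp8 (-0.51) and Birc5 lower, and all 3 other scalings put the median below 0. Higher were neutrophil (0.82, 0.0463) and atrial markers (0.20, 0.0464, with Myot and Clu) and glycolysis (0.15, 0.0463), whose median was below 0 with either quantile scaling. Mesothelial, endothelial and macrophage calls held without any 1 array. Smooth muscle was lost without cardioGRKO_2month replicate 3 (0.0753), mast cells without cardioGRKO_2month replicate 1 (0.0607), and adipocytes without that array, cardioGRKO_1month replicate 1 or cardioGRKO_2month replicate 2 (up to 0.128). The apoptosis call was lost without cardioGRKO_1month replicate 2, GRflox_2month replicate 1 or 2, or cardioGRKO_2month replicate 2 or 3 (up to 0.212). Neutrophils (up to 0.528), atrial markers (up to 0.461), glycolysis (up to 0.408) and lung (up to 0.221) were lost without cardioGRKO_1month replicate 1 or cardioGRKO_2month replicate 1 or 2. They were also lost without GRflox_1month replicate 3 or cardioGRKO_1month replicate 2 (neutrophil), GRflox_2month replicate 2 or 3 (atrial), GRflox_2month replicate 1 or 2 (glycolysis), and those 2 arrays, GRflox_1month replicate 2, cardioGRKO_1month replicate 3 or cardioGRKO_2month replicate 3 (lung). With slide as a block the calls of neutrophil markers (median 0.00, adjusted p = 0.352) and glycolysis (0.18, 0.118) were lost. Of the 22 lists, 8 had a median that changed by more than 1.5 times without 1 array, and that of apoptosis changed sign. Of the 22 list calls 13 held in all 14 alternatives; 1 ended that of adipocytes (0.105), 5 neutrophils (up to 0.352), 7 each glycolysis (0.981), lung (0.321) and atrial markers (0.282), 8 apoptosis (0.240) and 11 oxidative stress defence (0.661).

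The number of genes changed with age in knockouts depended on single hearts and slides. It was 0 without cardioGRKO_1month replicate 3 or cardioGRKO_2month replicate 2, and 1 without cardioGRKO_1month replicate 1 or cardioGRKO_2month replicate 1 or 3. It was 30 without cardioGRKO_1month replicate 2, 44 without GRflox_2month replicate 3, and 91 to 93 without GRflox_1month replicate 1 or GRflox_2month replicate 1 or 2. It was 0 without the second scan day, where limma gave a median age effect on the cell cycle list of -0.59. With slide as a block it was also 0, with 1911 genes at an unadjusted p under 0.05 by limma. All 176 called genes that could be fitted kept their direction there. In these 2 fits the log2 fold changes of the called genes were, as a median, 0.985 times and 1.02 times their values in the main fit. The genes were called on the same arrays, which favours ratios near 1.

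The 31 measured genes of the ion channel and conduction list did not pass in the knockouts at either age, as single genes over all genes or as a list. The channel genes Kcnj14 and Cngb3, which passed at 2 months, are not on this list. At 1 month 0 of 31 passed over all genes and 3 were higher (Cacna1h 0.71 and Cacna1g 0.59 among them) and 1 lower (Kcnv2 -2.46) when adjusted over the list alone (camera adjusted p = 0.968). At 2 months 0 passed over all genes and 3 were higher (Cacna1h 0.73 and Cacna1g 0.56 among them) and 3 lower, Kcnv2 (-2.37) among them, when adjusted over the list alone (adjusted p = 0.852). The list's smallest adjusted p over the 5 comparisons was 0.344, in the age effect in knockouts. In the prostaglandin list Ptgds fell at 2 months, and Prxl2b (0.48) was higher when adjusted over the list alone (camera adjusted p = 0.84). The dystrophin complex list at 2 months had 0 of 26 past over all genes, with Nos1 (1.56, SE 0.31) higher and Dmd (-0.71, SE 0.12) lower when adjusted over the list alone (adjusted p = 0.9).

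A set of 11 other lists did not move by camera in any of the 5 comparisons, with these smallest adjusted p-values. They were prostaglandin synthesis (0.745), the circadian clock (0.128), inflammatory cytokines (0.098), renin-angiotensin and adrenergic signalling (0.543) and the unfolded protein response (0.417). The others were p38 phosphatases (0.212), T and B lymphocytes (0.0634), thymus (0.417), erythroid cells (0.292), Schwann cells and neurons (0.312) and sex check genes (0.149). Uchl1, of the Schwann and neuron list, rose at 2 months in the knockouts, and Akap6 (0.54) and Nr4a1 (1.13) rose with age in the knockouts. The lymphocyte markers had a median of 0.41 in the 2-month knockouts, where 1 of the 3 arrays came from slide 4.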

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

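The tests of the scan day, of the slides, of the age of the animals and of the strongest list per relabeling were chosen only after the result was seen; the other relabelings were planned.

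The cell cycle list stood out because its knockout effect differed between the ages (median 0.61, camera adjusted p = 2.24e-27), with a median of -0.40 at 1 month and 0.31 at 2 months. The 1-month median leaned on GRflox_1month replicate 2, which had the highest score (1.214, against 0.685 and 0.432 in the other controls); without it the median was -0.222 and the difference between the ages 0.485. Of 100 relabelings within each age, 3 gave a median difference as large, the real one included (highest other 0.670). That share ignores the choice of this list among all lists tested, but 1 of 100, the real one, had a strongest list with a camera p as low (lowest other 4.03e-23, for matrix genes). Both argue against chance, although the adjusted p was 0.175 with an estimated correlation. Without the arrays of the second scan day the difference was 0.866, which argues against that day as the whole cause. The shift of -0.401 at 1 month cannot be told apart from slide 1, which held every 1-month control and no knockout. Older animals among the 1-month knockouts also stay open: their matrix score was -0.022 from the controls (SE 0.0987) where the same share of the age change would need -0.200, 1.81 SE away, and a delayed or altered growth in the knockouts was not tested further.

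Other lists whose knockout effect differed between the ages by camera were oxidative phosphorylation (adjusted p = 2.55e-05), fetal and hypertrophy genes (3.6e-05), sarcomere genes (0.000308), matrix and fibrosis (0.00155), ventricular cardiomyocyte markers (0.00753), apoptosis and p53 targets (0.00856) and macrophage markers (0.0402). In all 8 lists moved, while 70 of 100 relabelings within each age moved as many (highest other 24), so chance is not excluded for their number. For single genes the difference test gave 0 by limma (292 at an unadjusted p under 0.05), which all 100 relabelings reached. The highest of the others, 151, kept the labels at 1 month and reversed them at 2 months. It thus measures the effect shared by the ages. Another relabeling gave 78, for a reason that was not tested.

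The 5 genes changed in the knockouts at both ages were reached by 1 of 100 relabelings, the real one (highest other 1), which argues against chance. For the genes called at each age, 1 of 10 splits of the 6 arrays, the real one, gave as many at 1 month (6; highest other 0) and at 2 months (29; highest other 1), and 10 splits are too few for a share under 0.05. Without the second scan day the log2 fold changes of the called genes were 1.01 times (1 month, 6 of 6 in the same direction) and 1.02 times (2 months, 29 of 29) their values as a median. The median SE rose from 0.139 to 0.167 and from 0.154 to 0.177, and calls ended with fewer arrays. These genes were called on a fit that held the remaining arrays, which favours ratios near 1, so scan day is not excluded. The 6 genes called at 1 month had over the 6 arrays of 2 months, none of them on slide 1, 1.16 times their 1-month value as a median, and within slide 3 alone 1.19 times, so slide 1 is argued against as the whole cause for them. Within slide 3 the ratio was 1.04 for the 2-month genes, where a slide difference alone would give about 0. Both ratios within slide 3 rest on 1 control, assumed to vary like the other groups, and 2 knockouts. The 2-month genes were also called on a fit that included these arrays, which favours a ratio near 1, so slides are not excluded for them. Cre itself stays open, since 0 groups carried Cre with an intact receptor gene.

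For lists, 6 of 10 splits moved as many as the real 14 at 1 month (highest other 21) and 5 of 10 as many as the real 9 at 2 months (highest other 23). With age, 10 of 10 splits of the controls moved at least the real 11 lists (highest other 23), and 1 of 10 of the knockouts moved the real 22 (highest other 18). For genes with age, 1 of 10 splits gave as many in controls (483; highest other 1) and in knockouts (177; highest other 3). Other splits of the same arrays thus reached the numbers of lists at 1 month, at 2 months and with age in controls. Those numbers do not stand out from chance. For the remaining counts the real split alone reached the number, and 10 splits are too few for a share under 0.05.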

How the results depend on the processing

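Leaving out the second scan day or the 3 arrays that stood apart, scan day as a block, and array weights were tests chosen only after the result was seen.

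In the order genes changed in knockout at 1 month, genes changed in knockout at 2 months, genes changed with age in controls, genes changed with age in knockouts and genes changed in knockout at both ages, the counts were 6, 29, 483, 177 and 5. Only counts that moved by more than 1.5 times are given below. With normexp background and quantile scaling the first was 11 and the last 11. With quantile scaling of the processed signal the age count in knockouts was 105 and the last 8. With the median in place of the 75th percentile they were 0, 3, 76, 0 and 0, with 691, 484, 1978 and 1064 genes at an unadjusted p under 0.05 by limma. The cause was not tested.

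With no filter on dim probes the counts of genes changed in knockout at 2 months, genes changed with age in controls and genes changed with age in knockouts were 15, 281 and 28, where more genes were tested, and with probes well above background on all 12 arrays all were higher, 12, 50, 734, 408 and 10, where fewer were. With the mean of the probes of a gene the age count in knockouts was 40. A limit of adjusted p under 0.1 at both ages gave 11 shared genes. With trended and robust moderation of variances the 5 counts were 17, 81, 766, 446 and 15; the cause was not tested.

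With slide as a random block the counts at 1 month, with age in controls, with age in knockouts and at both ages were 3, 245, 71 and 3. With slide as a fixed block those at 2 months and with age in knockouts were 0 and 0 by limma (950 and 1911 at an unadjusted p under 0.05), and within the slide that holds both groups at 2 months the count was 0 (890). The fixed block could not estimate comparisons with the 1-month controls, which shared a slide with no other group. Array numbers used as a replicate block gave 0 in all 5 (1521, 1801, 2195 and 2063 at an unadjusted p under 0.05 in the single comparisons), with fewer degrees of freedom. For knockouts and controls of the same age, correlations of arrays with the same number ran from -0.056 to 0.494, and the same number was the best partner in 4 of 6, so a pairing of hearts is not excluded, while the labels give none. Only the 6 arrays of the 2 groups compared gave 0, 0, 8, 0 and 0 (1560, 1200, 2924 and 3414), with fewer arrays to estimate the spread.

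Without the 2 arrays of the second scan day the 5 counts, from genes changed in knockout at 1 month and genes changed in knockout at 2 months through genes changed with age in controls and genes changed with age in knockouts to those at both ages, were 0, 8, 244, 0 and 0, and without the 3 arrays that stand apart 1, 4, 169, 1 and 0, with 2 genes whose knockout effect differs between ages in place of 0. Fewer arrays were left in both. With scan day as a fixed block the age count in knockouts was 104. Array weights, between 0.37 and 5.69, gave 26, 1396, 2967, 3789 and 24, and were fitted to the same spread that they then reduced.

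Leaving out 1 array gave 0 to 4 genes at 1 month, 10 to 22 at 2 months, 155 to 442 genes changed with age in controls, 0 to 154 genes changed with age in knockouts, 0 to 4 at both ages and 0 in each case for the difference between ages.

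Among the genes called in the knockouts, all that were measured kept their direction in every alternative run. Over the alternatives, the log2 fold change of Myh7 at 1 month ran from 2.59 to 3.03, and it passed in 21 of 28. Of the values of the named genes reported here, 2774 kept direction and side of the threshold, 1504 no longer passed, 14 newly passed and 39 changed direction without passing before or after, such as Klf15 and Postn in the knockouts, while 0 changed direction with a call. For lists the numbers were 4413, 355, 157, 407 and 11. The 11, with the adjusted p after the change, were called lists whose call was lost and lists that passed in the other direction only in the alternative. Lost were interferon response at 1 month (0.235, without GRflox_1month replicate 2), neutrophil markers with age in knockouts (0.352, slide as a block) and, in the difference between ages, oxidative phosphorylation (0.369 with normexp background and quantile scaling, 0.186 with quantile scaling) and ventricular markers (0.698 with the former). Newly past were sarcomere genes and oxidative phosphorylation at 2 months (0.0224 each, array weights), adipocyte markers at 2 months (0.0077, without the 3 arrays that stand apart) and in the difference between ages (0.00922, without GRflox_1month replicate 3), and fatty acid oxidation in that difference (0.0393 and 0.0446 with the 2 quantile scalings). Over all arrays left out in turn, the adjusted p ran from 0.000139 to 0.466 for list interferon response (knockout at 1 month) and from 0.000195 to 0.931 for list cell type: adipocyte (difference between ages). Lists were not run for slide as a random block, each probe on its own, trended and robust moderation, or a fold of at least 1.5. The deposited table, each probe on its own and a fold of at least 1.5 left all 5 counts within 1.5 times. Since the deposited table equals the processed signal, its result was fixed in advance. It is still counted among the alternatives above and adds no support there. Signal over background limits the dim genes: Prr27 and Klk1b16 were well above background in 3 of 12 arrays. Their folds are lower bounds under the main processing only. Over the alternatives their log2 fold changes in the 2-month knockouts shrank to as little as -0.81 and -0.39.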

Other observations

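The average of the knockout effect over both ages, and the tests of it and of Prr27 and Klk1b16 below, were chosen only after the result was seen.

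The average knockout effect over both ages passed in 151 genes by limma, 80 higher and 71 lower (2603 at an unadjusted p under 0.05), and 1 of 100 relabelings within each age, the real one, gave as many (highest other 1), which argues against chance. All 151 had the same direction at both ages and 146 had groups that did not overlap at either age, which choosing them by their average on these arrays largely fixes. Myh7 rose by log2 2.57 (SE 0.15, 5.95-fold, adjusted p = 0.000266), while Nr3c1 fell by 1.07 (SE 0.09, adjusted p = 0.0015) and Ptgds fell by 1.52 (SE 0.13, adjusted p = 0.0015). Calcium channel genes Cacna1h (0.72) and Cacna1g (0.57) rose, as did Nos1 (1.40), Gdf15 (1.53), Bcl2 (1.09) and Eda2r (1.02). The Bcl2 value is that of 1 probe, while its other probes gave log2 0.05 and 0.43 at 1 month and 0.02 and 0.57 at 2 months. Kcnv2 fell by 2.42, Acot1 by 1.24, Fgf2 by 0.83, Pik3r1 by 0.78, Hand2 by 0.50, Hey2 by 0.49, Dmd by 0.48 and Ryr2 by 0.45. These genes, apart from Nr3c1, Myh7, Ptgds and Ryr2, were chosen after their values were seen.

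That count was 18 without the second scan day, of which 17 were among the 151, and 11 without the 3 arrays that stood apart. It was 116 with slide as a random block, 71 with scan day as a block, 188 with normexp background and quantile scaling, 132 with quantile scaling and 7 with median centring. Leaving out 1 array gave 57 (without cardioGRKO_1month replicate 3), 64 (cardioGRKO_2month replicate 2 or 3), 66 (GRflox_1month replicate 2 or cardioGRKO_1month replicate 2), 68 (cardioGRKO_2month replicate 1), 69 (cardioGRKO_1month replicate 1), 74 (GRflox_1month replicate 1), 84 (GRflox_2month replicate 3), 95 (GRflox_2month replicate 1), 98 (GRflox_2month replicate 2) and 107 (GRflox_1month replicate 3). Without the second scan day all 151 kept their direction and an unadjusted p under 0.05, with a median ratio of log2 fold changes of 1.01, but the genes were chosen on a fit that shares the remaining arrays. Across all genes the effects at the ages correlated with r = 0.381, and -0.032 without those arrays, so the shared part over all genes may follow scan day; genes are not independent replicates.

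Prr27 and Klk1b16 were well above background in the 2-month controls alone. Both were well above background there on slides 2 and 3 and on no other array of those slides. The 2 genes were picked for this pattern, so it is not a separate test of slides as the cause. The smallest difference within a slide was 2.98 (log2, Klk1b16), not a measured size since the other arrays lay near background. A candidate source, salivary gland tissue, stays open. The 34 measured of 38 listed salivary transcripts differed by a median of 0.127. The SE of their mean, taken over transcripts and not over hearts, was 0.0958. In the 14 that were well above background on all 12 arrays, a small share of gland might not show. Gland could raise the dimmer ones, yet most of these were not higher by 1 or more. Of the 34, 4 were higher by 1 or more in the 2-month controls, namely Prb1 (1.83), Klk1b1 (1.38), Klk1b21 (1.18) and Klk1b5 (1.06). None of the 34 separated these hearts from all others. No biological explanation was tested.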
